A study of Mus musculus with 12 samples.

How the data were processed

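RNA of mouse embryonic kidney was measured on a Notch-pathway oligonucleotide array, a membrane with 128 spots per array of which 120 were gene spots for 118 genes. The series held 12 arrays of 5 gestational stages, with 3 arrays at E12, 3 at E13, 2 at E14, 2 at E16 and 2 at E18 (embryonic days 12, 13, 14, 16 and 18). Per the labels' protocols, total RNA was isolated with TRIzol, amplified and labelled with biotin, and per the series' design text the hybridised membranes were read by chemiluminescence. The labels called the arrays of a stage technical replicates. Every p-value that compares arrays therefore measured only the spread between arrays, and whether the RNA of a stage came from 1 embryo or from a pool was not given in the sources used here.

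The deposited file of each array held 1 intensity per spot as a whole number, with no background column, and the image software was not given in the sources used here. Negative-control spots lay well above 0, so the deposited intensities were taken as not background-subtracted. The design fixed before the data were examined named a file with foreground and background columns and a file already corrected, and these files were taken to be neither. The background was therefore corrected by the normexp model with an offset of 50, fitted to the signal of all spots of an array. A deposited table of the whole series held a ratio per gene spot. From the values, each ratio was the signal minus the lowest spot of the array, divided by the mean of the 2 Ppia spots minus that lowest spot, and the lowest spot itself was empty. The lowest spot was a gene spot 502 to 777 signal units below the lowest negative control, so artificial-sequence controls stayed at 0.0133 to 0.0272 of Ppia in that table. Column medians of the ratio ran from 0.0874 to 0.194. The ratio table, on the log2 scale, served as an alternative, without Ppia because it is constant there by construction.

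After background correction, control spots were left out, values were put on the log2 scale, quantile-normalized over the 120 gene spots, and duplicate spots of a gene were averaged. With so few spots, quantile normalization gives identical values, and an SD of 0, to a gene that held the same rank on both arrays of a stage, as happened for Pparg at E18 and Jag1 at E16. A gene was tested if its signal exceeded the mean plus 2 SD of the 6 negative-control spots on every array of at least 1 stage. This left 106 genes, and 12 were not tested. A gene not above background on any array of a stage has only a bound there. The fold was then given as at least the bright stage's mean against, per array, the higher of the lowest signal among genes above background and the gene's own. Gene names are those of the array. Through their accessions 115 of the 118 matched the RefSeq gene table of assembly GRCm38.p6, 8 of them under a different current symbol: Aes is now Tle5, Figf Vegfd, Mycl1 Mycl, Mtap1b Map1b, Neurl Neurl1a, Pcaf Kat2b, Supt6h Supt6 and Wisp1 Ccn4. No genome build was named, so no coordinates are given.

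Median gene signal was 4435 to 9671.5 per array, the mean of the negative controls 772.5 to 3494.83 and their ratio 2.77 to 8.47. The number of arrays limits the precision. The median SD between arrays of a stage was 0.58 log2 units in the dimmest 36 genes, 0.40 in the next 35 and 0.14 in the brightest 35.

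Stages were compared with limma 3.58.1 in R 4.3.3, with 1 mean per stage over all 12 arrays and a shared spread (7 residual and 1.72 prior degrees of freedom). A moderated F test covered the 5 stages, and 7 contrasts covered each later stage against E12 and successive stages, all 2-sided. A linear trend over gestational day was fitted by limma to the 5 stage means, so that the stage was the unit. Adjusted p-values followed Benjamini and Hochberg over the genes tested, with a threshold of 0.05. For E18 minus E12, 16 gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Genes were named by a rule fixed at the same time. For E18 minus E12 the rule took all tested Notch receptors, ligands, proteases, modifiers and Hes and Hey targets, up to 10 rises and 10 falls past the threshold, up to 4 members with the smallest p of each other list, and the housekeeping genes. For other pairs it took up to 5 rises and 5 falls past the threshold, and for the trend the 10 smallest p in each direction. The values of 2 genes that the rule takes are not reported here, and both stayed in every fit and count. Replicate numbers were checked for pairing by correlating deviations from the stage means across genes. Between E12 and E13, the stages with 3 arrays, all 3 same-numbered pairs had an r above 0.1 (0.122 to 0.222), and 6 of 6 arrays correlated best with their own number, so the numbers were taken to pair these arrays, from the data and not from a label. With 3 arrays per stage, such a match can also arise by chance. The main fit held no block, and the replicate number as a block was an alternative. Similarity of arrays was tested with 100000 permutations of the stage labels. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

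The procedure was tested on simulated data with 20 of the 106 genes changed, in 50 runs. The simulated arrays kept the real array backgrounds and the spread of each gene between arrays, with as many rises as falls. They had no differences in scale between arrays and no variation between stages beyond the spread between arrays. The rates below hold for those settings only. For E18 minus E12 it recovered 46.1% of 2-fold and 79.2% of 4-fold changes, with 0.8 false calls per run. For the trend it recovered 28.5% of 2-fold and 61.7% of 4-fold changes, with 0.64 false calls per run.

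Alternatives chosen before the data were examined were scaling to array medians, scaling to housekeeping genes, no normalization between arrays, no background correction, the deposited ratio table, no filter, the replicate number as a block, only the arrays of the 2 stages compared, stage as a random block or stage order for the trend, and leaving out each array or stage. Alternatives chosen after seeing the data were a prior that follows the mean signal, a background taken from the negative controls, and leaving out the 3 arrays whose negative-control mean exceeded 2000 (replicate 1 of E13, E16 and E18), which leaves 1 array each at E16 and E18 that is assumed to vary like the other stages.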

Results

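Notch signalling, a pathway in which membrane ligands on 1 cell activate receptors on its neighbour, was profiled in mouse embryonic kidney at E12, E13, E14, E16 and E18 on 12 arrays, 3 at each of the first stages E12 and E13 and 2 at each later stage. Of the 118 genes on the array, 106 were above background on every array of at least 1 stage. The 12 that were not were Cd44, Cdkn1b, Fzd10, Fzd4, Il2ra, Map2k7, Mmp7, Pcaf, Pdpk1, Ptch1, Sh2d1a and Shh. Between 94 and 112 genes were above background per array. The median gene signal was 4435 to 9671.5, which was 2.77 to 8.47 times the array's mean negative control. Arrays of a stage were technical replicates, so the stage differences below are set against array spread only.

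**Figure D1:**
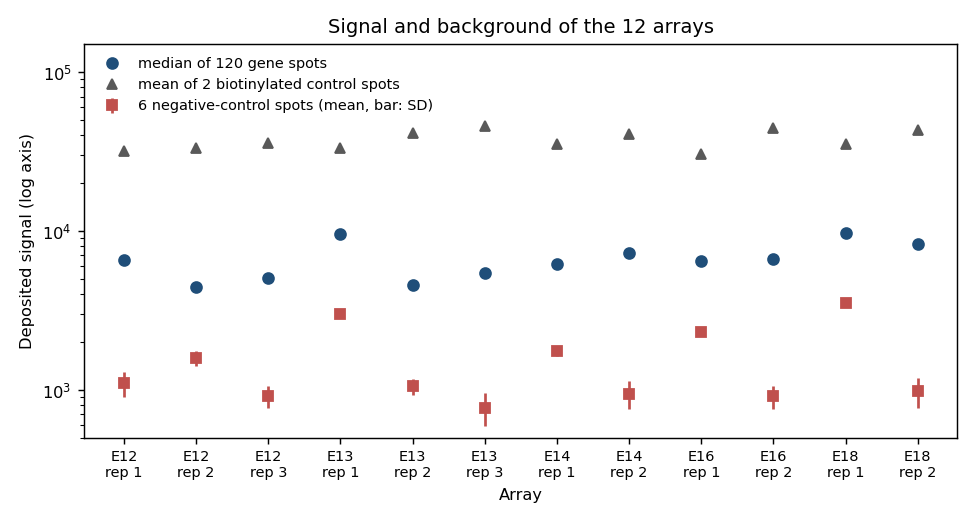
Deposited signal (log axis) of each of the 12 arrays, with the median of 120 gene spots (circles), the mean of 2 biotinylated positive controls (triangles) and the mean of 6 negative controls (squares, bars: SD). The negative-control mean ran from 772.5 to 3494.83 and exceeded 2000 on replicate 1 of E13, E16 and E18.

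The first comparison set the last stage against the first. Jag1, a Notch ligand of the developing nephron, rose 1.81-fold from E12 to E18. Its normalized log2 signal was 13.49 ± 0.17 (SD, n = 3) at E12 and 14.34 ± 0.06 (SD, n = 2) at E18, a difference of 0.85 (SE 0.17, limma adjusted p = 0.0476). Krt1, a keratin of differentiating epidermis, fell 1.61-fold, from 12.18 ± 0.08 (SD, n = 3) to 11.49 ± 0.06 (SD, n = 2), a difference of -0.69 (SE 0.14, limma adjusted p = 0.0476). For both genes, both E18 arrays lay on the same side of all 3 E12 arrays. Jag1 and Krt1 were the 2 genes past the threshold among 106, and 18 had an unadjusted p under 0.05. Neither call held with no filter, with the replicate number as a block or with only the arrays of the 2 stages. That of Krt1 was also lost with the prior that follows the mean signal. Both calls were lost when E12 replicate 1, 2 or 3, E13 replicate 2 or 3, E14 replicate 1 or 2, or E18 replicate 1 or 2 was left out (adjusted p up to 0.257), while over the 12 fits without 1 array the difference ran from 0.77 to 0.98 for Jag1 and from -0.73 to -0.64 for Krt1. They were also lost without the 3 arrays of highest background, where Jag1 differed by 0.93 and Krt1 by -0.66 (adjusted p = 0.144 for both), and under each other scaling, where Krt1 ranged from -0.82 to -0.13 and Jag1 from 0.42 to 1.11.

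Among the 5 Notch ligands tested, Jag1 rose and the other 4 did not pass the test. Jag2 differed by 1.07 (SE 0.50), Dll1 by 0.40 (SE 0.62), Dll4 by 0.11 (SE 0.49) and Dll3 by -0.68 (SE 0.41) log2 units. Jag2 was above background on 1 of 3 E12 arrays, so its difference rests partly on values near background. Adjusted over the list alone, 1 ligand was higher and 0 were lower. None of the 4 receptors passed. Notch1 differed by 0.70 (SE 0.28, adjusted p = 0.224), Notch2 by 0.39 (SE 0.38), Notch4 by 0.17 (SE 0.42) and Notch3 by 0.03 (SE 0.34), and under scaling to array medians Notch3 and Notch4 were at -0.12 and -0.04. That scaling moved the median of all genes by -0.44, and no normalization moved it by 0.24. As lists, the ligands (median 0.40, camera adjusted p = 0.669) and the receptors (median 0.28, camera adjusted p = 0.669) did not pass.

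Enzymes that cut the receptor, the gamma-secretase subunits and ADAM proteases, had 0 of 7 members past the test. Psen2, a catalytic presenilin, differed by 0.63 (SE 0.41), Adam10 by 0.49 (SE 0.57), Psenen by 0.06 (SE 0.17), Ncstn by 0.02 (SE 0.13), Adam17 by -0.09 (SE 0.15) and Aph1a by -0.12 (SE 0.21). Of the 11 modifiers and trafficking genes, 0 passed. The largest differences in size were those of Numbl at -0.57 (SE 0.20, adjusted p = 0.155) and Numb at 0.47 (SE 0.24, adjusted p = 0.408), both related to a Notch inhibitor that is partitioned at cell division. The fringe glycosyltransferases Mfng, Rfng and Lfng differed by 0.42, 0.35 and 0.34, and Sel1l, Pofut1, Dtx1, Neurl, Dtx3 and Dtx2 by 0.25, 0.24, 0.08, -0.01, -0.07 and -0.21. None of the 6 Hes and Hey genes, a family that includes transcriptional repressors induced by Notch, passed. Hes1 differed by 0.12 (SE 0.11), Hes5 by 0.10 (SE 0.47), Heyl by 0.00 (SE 0.35), Hey1 by -0.10 (SE 0.12), Hes6 by -0.18 (SE 0.11) and Hey2 by -0.51 (SE 0.39). The camera adjusted p was 0.669 for the proteases, 0.777 for the modifiers and 0.669 for the Hes and Hey genes.

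**Figure D2:**
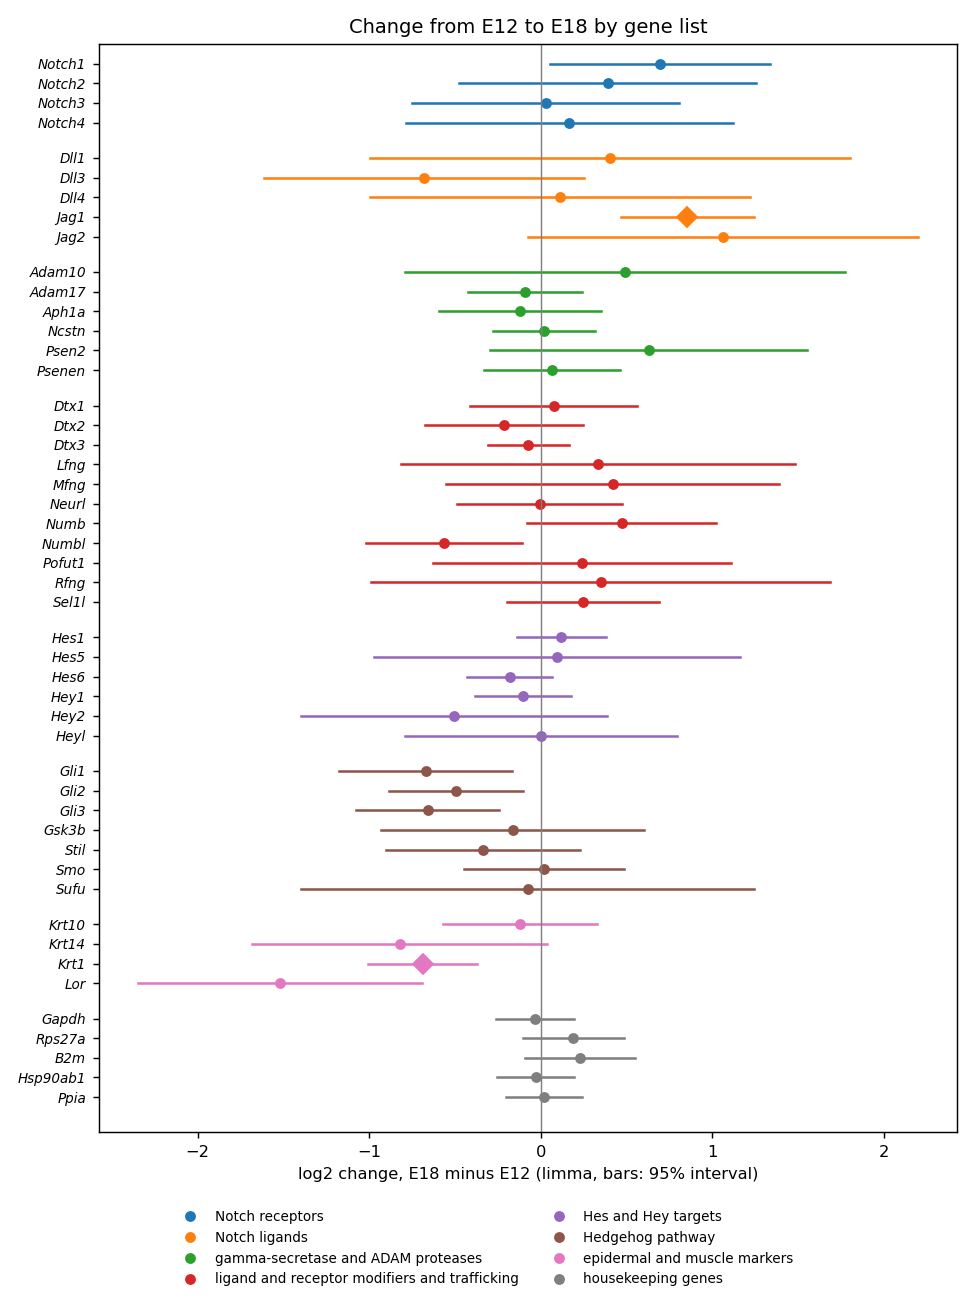
Log2 change from E12 to E18 (x axis, log2 units; bars: 95% interval from limma) of tested genes (y axis) in 8 of the 16 lists, coloured by list, with diamonds for adjusted p under 0.05. Jag1 at 0.85 and Krt1 at -0.69 are the 2 diamonds.

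The 4 tested genes of a list of epidermal and muscle markers, all of keratinocytes, were lower at E18 as a list. Krt1 fell, and Lor, a cornified-envelope protein, Krt14, a basal keratin, and Krt10 differed by -1.52 (SE 0.36, adjusted p = 0.065), -0.82 (SE 0.38, adjusted p = 0.313) and -0.12 (SE 0.20). The median over these 4 genes was -0.75 (camera adjusted p = 0.0119, fry adjusted p = 0.0207), with adjusted p = 0.262 with an estimated correlation. Adjusted over the list alone, 2 of 4 were lower. The array held no muscle gene of the list. Of 2 keratinocyte genes outside the list, Krt5 differed by -0.17 (SE 0.48, adjusted p = 0.944). Ivl was above background on 1 of 3 E12 arrays and on neither E18 array. With these 2 added, a choice made after the values were seen, the median was -0.43. The list's call was lost under each of the 4 other scalings, with medians from -1.01 to -0.32 and adjusted p of 0.131 to 0.184.

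Of the 7 Hedgehog pathway genes tested, 0 passed over all genes and 3 were lower adjusted over the list alone. These were the Gli transcription factors, with Gli1 at -0.67 (SE 0.22), Gli3 at -0.66 (SE 0.18) and Gli2 at -0.49 (SE 0.17), and Stil was at -0.34 (SE 0.25). The list's median was -0.34 (camera adjusted p = 0.0567, and adjusted p = 0.262 with an estimated correlation). Among cell cycle and survival genes, Fos, an immediate early transcription factor, was at 1.27 (SE 0.33, adjusted p = 0.0743), Ccne1, a G1/S cyclin, at -0.73 (SE 0.18, adjusted p = 0.065), Mycl1 at -0.68 (SE 0.22) and Cdc16 at -0.77 (SE 0.47). Adjusted over the list alone, 1 was higher and 2 were lower. NF-kB and immune genes had 2 higher and 1 lower adjusted over the list alone. Gbp2, an interferon-induced GTPase, was at 0.97 (SE 0.30), Nfkb2 at 0.62 (SE 0.19) and Nfkb1 at 0.27 (SE 0.12). Il17b, a cytokine of the interleukin-17 family, was above background on all 3 E12 arrays and on neither E18 array, a level at least 4.46-fold lower (adjusted p = 0.065, not past the threshold). Among the 21 other Notch targets tested, 1 (Krt1) was lower over all genes, and 4 were higher and 4 lower adjusted over the list alone.

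The remaining lists had 0 genes past the test over all genes or adjusted over the list alone. The median was 0.13 for nuclear co-activators (camera adjusted p = 0.72; Ep300 0.74, Maml1 0.13, Rbpj 0.13, Supt6h -0.19) and -0.10 for co-repressors (camera adjusted p = 0.669; Nrarp 0.55, hr -0.63, Tle1 -0.48). It was -0.08 for the Wnt pathway (camera adjusted p = 0.72), with Fzd6 at 0.58 (SE 0.47), Fzd7 at 0.41 (SE 0.38), Fzd3 at -0.91 (SE 0.54) and Ctnnb1 at -0.17 (SE 0.14). Fzd3 was above background on 1 of 2 E18 arrays. Endothelial markers had a median of 0.06 (camera adjusted p = 0.784) and blood-cell markers of 0.16 (camera adjusted p = 0.72), with Lmo2 at 0.20, Pax5 at 0.67, Ptcra at 0.16 and Ifng at -0.14. The housekeeping genes were at 0.23 for B2m, 0.19 for Rps27a, 0.02 for Ppia, -0.03 for Hsp90ab1 and -0.03 for Gapdh, and Ppia was at -0.57 under scaling to array medians. On average their signal was 0.917 (B2m) to 1.11 (Gapdh) times that of the positive controls. Quantile normalization works by rank and leaves genes this bright little room to move, so these values say little about their stability.

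Each other stage was then set against E12. At E16, Krt1 fell 2.06-fold (difference -1.04, SE 0.14, limma adjusted p = 0.00491), to 11.14 ± 0.25 (SD, n = 2). Jag1 rose 1.93-fold (difference 0.95, SE 0.17, limma adjusted p = 0.0212), to a mean of 14.43 on 2 arrays of identical rank. At E14, Krt14 fell 4.85-fold, from 14.06 ± 0.52 (SD, n = 3) to 11.78 ± 0.66 (SD, n = 2) (difference -2.28, SE 0.38, limma adjusted p = 0.0238). In each of these comparisons, both later arrays lay on the same side of all 3 E12 arrays. Over all settings the differences ran from -1.27 to -0.76 for Krt1 and from 0.83 to 1.09 for Jag1 at E16, and from -2.70 to -1.83 for Krt14 at E14. With only the arrays of the 2 stages, each of these calls was lost. Krt1 at E16 also lost its call with the prior that follows the mean signal, and Jag1 at E16 with the replicate number as a block. Krt1 at E16 kept its call in all 12 fits without 1 array. At E13, 0 genes passed the limma test and 5 had an unadjusted p under 0.05, with Jag1 at 0.81 (SE 0.15, adjusted p = 0.059). Jag1 at E16 lost its call without E12 replicate 2 or 3, or either array of E16 or E18 (adjusted p up to 0.124), and Krt14 at E14 without E12 replicate 1 or 2, E13 replicate 2, E14 replicate 1 or either E16 array (adjusted p up to 0.0979). The calls of Krt1 and Jag1 at E16 were also lost under each of the 4 other scalings, that of Krt14 at E14 with housekeeping scaling (adjusted p = 0.0926) and no normalization (adjusted p = 0.053), and without the 3 arrays of highest background the adjusted p was 0.228 for Krt1 and 0.266 for Jag1 at E16 and 0.142 for Krt14 at E14.

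Between successive stages, Krt1 fell 1.83-fold from E14 to E16 (difference -0.87, SE 0.15, limma adjusted p = 0.0358), with both E16 arrays below both E14 arrays. No gene passed the limma test from E13 to E14 or from E16 to E18, where 6 and 4 genes had an unadjusted p under 0.05. The call for Krt1 was lost when any array other than E16 replicate 2 was left out (adjusted p up to 0.232). It was also lost under each of the 4 other scalings, with the replicate block, with the prior that follows the mean signal and with the 2 stages alone. The difference was -0.70 without the 3 arrays of highest background, and ran from -1.15 to -0.69 over all settings. Over all 5 stages, Krt1 was the 1 gene past the F test (limma adjusted p = 0.0321), and 12 genes had an unadjusted p under 0.05. The count fell to 0 when any array other than E16 replicate 2 was left out, and with housekeeping scaling, no normalization, the deposited ratios, or without the 3 arrays of highest background. Jag1, Krt14 and Fos each had an adjusted p of 0.0725.

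Over gestational day, with each stage as 1 value, Pparg rose and Il17b fell. Pparg, a nuclear receptor of lipid metabolism, rose by 0.18 log2 units per day (SE 0.02, limma adjusted p = 0.0214), from 11.20 ± 0.35 (SD, n = 3) at E12 to 12.29 on both E18 arrays. The slope of Il17b was -0.51 log2 units per day (SE 0.06, limma adjusted p = 0.0214), from 12.09 ± 0.79 (SD, n = 3) at E12 through 10.77 ± 0.53 (SD, n = 2) at E14. It was above background on 1 of 2 arrays at E16 and on 0 of 2 at E18, so later values are bounds, and the slope, its SE and its p come from a fit that took them as measured. The next slopes, not past the test, were 0.17 for Gbp2 (adjusted p = 0.0565), 0.16 for Il6st, 0.14 for Stat6, 0.14 for Fzd6, 0.10 for Notch1, 0.26 for Fos, 0.09 for Cflar, 0.08 for Nfkb2, -0.11 for Gli3 (adjusted p = 0.0915), -0.11 for Numbl, -0.11 for Ccne1, -0.30 for Lor, -0.11 for hr, -0.12 for Mycl1, -0.14 for Fzd3, -0.15 for Krt1 and -0.11 for Cdc16. In all, 18 genes had an unadjusted p under 0.05. Both calls were lost when any 1 stage was left out (adjusted p of 0.0518 to 0.193), and without E14 replicate 2 or E16 replicate 2, and that of Pparg also without E16 replicate 1 (adjusted p up to 0.318) and under scaling to array medians (slope 0.16, adjusted p = 0.075). Without the 3 arrays of highest background the slopes were 0.21 for Pparg (adjusted p = 0.14) and -0.40 for Il17b (adjusted p = 0.0668).

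**Figure D3:**
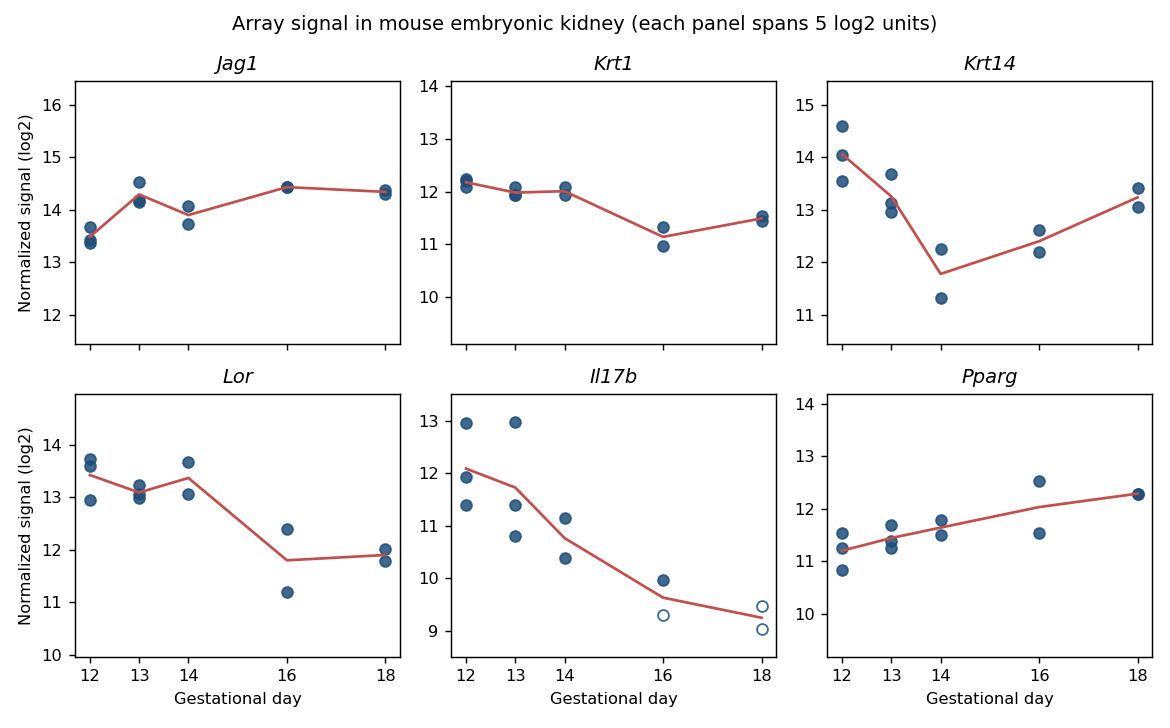
Normalized log2 signal (y axis, each panel spanning 5 log2 units) against gestational day (x axis) of 6 genes, with a point per array and a line through the stage means. Filled points are above background and open points are not: Il17b is open on 1 of 2 arrays at E16 and on both at E18.

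Arrays of 1 stage were compared with arrays of other stages across the 106 genes. The mean Pearson's r between arrays, which is across genes and not across independent replicates, was 0.93 within stages and 0.927 between them (1-sided permutation p = 0.325, adjusted p = 0.325 over 2 gene sets). Over the 53 genes of highest mean signal it was 0.877 within and 0.841 between stages (1-sided permutation p = 0.0235, adjusted p = 0.047).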

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

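The prior that follows the mean signal, the background from negative controls and the fit without the 3 arrays of highest background were chosen after seeing the data. The cause was not tested for any change given here, and fits that leave arrays out also have fewer arrays. Counts below need not hold the same genes. In E18 minus E12 and in E16 minus E12, Krt1 lost its call with the prior that follows the mean signal. Jag1 and Krt1 both lost theirs with array medians, so the 1 gene counted there was neither. E18 minus E12 had 2 genes past the threshold, and 1 with array medians, 0 with housekeeping scaling, no normalization, the deposited ratios, no filter, the 2 stages alone and without the 3 arrays, and 4 with the prior that follows the signal. E16 minus E12 had 2, and 1 with array medians, 4 with no background correction or with that prior, and 0 with housekeeping scaling, no normalization, the deposited ratios, the 2 stages alone and without the 3 arrays. E14 minus E12 had 1, and 0 with housekeeping scaling, no normalization, the 2 stages alone and without the 3 arrays. E13 minus E12 had 0, and 1 with no background correction or with that prior. E16 minus E14 had 1, and 0 with array medians, housekeeping scaling, no normalization, the deposited ratios, that prior, the 2 stages alone and without the 3 arrays. The F test had 1, and 2 with array medians, 6 with that prior, and 0 with housekeeping scaling, no normalization, the deposited ratios and without the 3 arrays. The trend had 2, and 12 with that prior (8 higher, 4 lower), 12 with stage as a random block (4 higher, 8 lower) and 0 without the 3 arrays. Stage as a random block had a consensus correlation of -0.14 between arrays of a stage. A value below 0 lets arrays of a stage count for more than independent samples. The 12 trend calls of that block therefore do not take the stage as the unit. Of the lists 1 passed, and 0 with array medians, housekeeping scaling, no normalization, the deposited ratios, the prior that follows the signal or an estimated correlation. Leaving out 1 array or stage gave 0 to 7 genes for E18 minus E12, 1 to 3 for E16 minus E12, 0 to 1 for E14 minus E12, 0 to 0 for E13 minus E12, 0 to 1 for E14 minus E13, 0 to 2 for E16 minus E14, 0 to 0 for E18 minus E16, 0 to 3 for the F test, 0 to 3 for the trend and 1 to 2 lists. The 7 calls came without E16 replicate 2. Signal over background, from 2.77 to 8.47 per array, limits the dim genes most.

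Among named genes, 51 values changed sign, none of them of a gene past the threshold in that comparison. With array medians, which shift the median of all genes by -0.44, E18 minus E12 was -0.12 for Notch3, -0.038 for Notch4, -0.26 for Dll4, -0.49 for Ncstn, -0.41 for Psenen, -0.44 for Dtx1, -0.030 for Lfng, -0.080 for Mfng, 0.037 for Neurl, -0.16 for Pofut1, -0.18 for Rfng, -0.21 for Sel1l, -0.49 for Hes1, -0.32 for Heyl, -0.48 for Maml1, -0.21 for Rbpj, -0.21 for Fzd7, -0.21 for Nfkb1, -0.32 for Lmo2, -0.035 for Ptcra, -0.41 for Rps27a, -0.30 for B2m and -0.57 for Ppia. With housekeeping scaling it was 0.57 for Neurl, 0.018 for Supt6h and -0.037 for Ppia. With no normalization it was 0.075 for Adam17, 0.10 for Aph1a, 0.0097 for Dtx3, 0.72 for Neurl, 0.12 for Hey1, 0.089 for Hey2, 0.18 for Supt6h, 0.047 for Krt10, 0.011 for Gapdh and 0.097 for Hsp90ab1. With no background correction it was -0.0010 for Heyl, and in the deposited ratios 0.57 for Neurl, 0.051 for Supt6h and -0.33 for Pax5. Without the 3 arrays it was -0.35 for Notch4, -0.031 for Dll4, -0.11 for Psenen, -0.024 for Rfng, 0.0089 for Krt10 and 0.00055 for Hsp90ab1. Leaving out 1 array turned the sign of 18 genes in E18 minus E12, with ranges of -0.23 to 0.30 for Notch3, -0.085 to 0.49 for Dll4, -0.31 to 0.56 for Hes5, -0.34 to 0.69 for Notch4, -0.26 to 0.81 for Lfng, -0.11 to 0.064 for Neurl, -0.021 to 0.52 for Pofut1, -0.065 to 0.84 for Rfng, -0.27 to 0.25 for Heyl, -0.21 to 0.060 for Aph1a, -0.0084 to 0.066 for Ncstn, -0.34 to 1.18 for Pax5, -0.24 to 0.45 for Ptcra, -0.11 to 0.24 for Psenen, -0.32 to 0.0077 for Krt10, -0.43 to 0.053 for Supt6h, -0.32 to 0.047 for Ifng and -0.013 to 0.058 for Ppia.

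With the replicate number as a block, calls went from 2 to 0 for E18 minus E12, from 2 to 1 for E16 minus E12, from 1 to 0 for E16 minus E14 and from 1 to 0 for the F test, and other counts did not move. Over the 5 stages the deviations did not pair the arrays by number throughout: of 21 same-numbered pairs, 8 had an r above 0.1. The r ran from -0.378 to 0.367, and between stages of 2 arrays both pairs have the same r by construction. The highest r was that of E14 with E18. Replicate 1 also had the lowest mean positive control in each stage, so the numbers were not without structure. E12 and E13 were the stages taken as paired, and there the block left 0 calls in E13 minus E12. In that comparison 7 genes had an unadjusted p under 0.05 with the block, against 5. With the block, E18 minus E12 was -0.064 for Notch3, -0.029 for Ncstn, -0.028 for Psenen, 0.099 for Neurl and -0.10 for Ptcra.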

Other observations

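Tests chosen only after the results were seen were those of epidermal cells and of normalization for the keratinocyte genes, and the stage orders without Il17b. The fits without the 3 arrays of highest background were added after seeing the data, with bounds set before their own values were seen. The demand that a value clear its bound by its spread (2 SE, or a 95% limit) was added after the values were seen, and it withheld an exclusion in 3 tests.

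Jag1 and Krt14, each past the test in a comparison with E12, and Lor and Fos, past none and picked after their values were seen, had the following stage means. Jag1 stood at 13.49 at E12, 14.29 ± 0.21 (SD, n = 3) at E13, 13.90 ± 0.25 (SD, n = 2) at E14, 14.43 at E16 and 14.34 at E18. Krt14 went from 14.06 at E12 to 13.26 ± 0.38 (SD, n = 3) at E13 and 11.78 at E14, and stood at 12.40 ± 0.29 (SD, n = 2) at E16 and 13.24 ± 0.25 (SD, n = 2) at E18. Lor was at 13.42, 13.09 and 13.37 at E12, E13 and E14, and at 11.80 ± 0.84 and 11.90 ± 0.16 (SD, n = 2) at E16 and E18. Fos was at 12.48 at E12, 11.87 at E13, 11.90 at E14, 12.75 at E16 and 13.75 at E18. Over the 5 stages the limma F test gave an adjusted p of 0.0725 for Jag1, Krt14 and Fos and 0.0789 for Lor, so these courses did not pass it.

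From E12 to E18, 3 lists passed the fry test for change in either direction. It gave an adjusted p of 1.25e-06 for NF-kB and immune genes, 4.04e-05 for other Notch targets and 0.000506 for cell cycle and survival genes. The directional fry test did not pass for these lists (adjusted p = 0.439, 0.556 and 0.579). The test for either direction was run at the main setting only, and arrays were not regrouped for it. Over all genes, 0 members of the NF-kB and cell cycle lists passed the limma test, and 1 (Krt1) of the other Notch targets. Il17b, not above background at E18, belongs to the NF-kB and immune genes and to the other Notch targets, so the values of both lists hold a bound. The 3 calls are not separate findings: 8 of the 8 NF-kB and immune genes and 5 of the 7 cell cycle and survival genes are also among the 21 other Notch targets, and camera, which tests for a shared direction, gave an adjusted p of 0.669 for each (0.772 with an estimated correlation).

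Chance was examined by regrouping the arrays. Of 100 splits of the 12 arrays, 7 gave as many genes past the F test as the real 1 (highest other split 3), and 14 gave as many at an unadjusted p under 0.05 as the real 12 (highest other 27), so chance cannot be excluded for either count. For E13 minus E12 the real count was 0, so all 10 splits gave at least as many by necessity (highest other 1), which says nothing about chance. Of the 60 orders of the 5 stage means, 1, the real order itself, gave 2 genes with a trend (highest other 1), and 1, again the real order, gave 18 at an unadjusted p under 0.05 (highest other 17). On all arrays the real order thus gave the most genes for both counts, by a margin of 1 gene each. The count of 2 fell to 0 without E14 replicate 2, without E16 replicate 2 or without any 1 stage, so chance order is not excluded for it. Il17b, 1 of the 2 genes, has values below background at E16 and E18. Without it, a check added after the values were seen, 3 of the 60 orders gave as many genes as the real 1 (highest other 1). For the genes past the test the real order therefore stood out only with Il17b. The real 17 at an unadjusted p under 0.05 was matched by no other order (highest other 16). The margin was 1 gene, and the orders were not rerun without an array or a stage. Chance order is therefore not excluded for that count either.

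Over all 106 genes, no greater similarity within stages than between them was detected. Dim genes near background may account for this: over the 53 genes of highest signal the similarity within stages was greater (1-sided permutation p = 0.0235). Array background stays open, since the first principal component (23.3% of the variance) correlated with log2 background at an absolute Pearson's r of 0.0578 (permutation p = 0.858; Spearman's rho 0.35, permutation p = 0.266; r 0.0597 without the 2 arrays farthest from the median), but 12 arrays allow an r of up to 0.611. It was 1 of 2 relations computed (adjusted p = 0.858), the other being with gestational day, which has 5 independent values and is not reported as a correlation. The stage labels were what was permuted, so the result over the 53 genes is one of similarity by stage. Whether it came from a biological difference between stages was not tested.

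Keratinocyte genes were lower at E18 than at E12 as a list, a camera call lost with an estimated correlation (adjusted p = 0.262). The 3 arrays of highest background stay open: without them the median of the 4 genes went from -0.755 to -0.857 (SE over members 0.366, camera adjusted p = 0.0318 at the preset correlation), which is no smaller, but E18 then rests on 1 array and the value is within 2 SE of the bound of -0.3. Normalization stays open too: the median stayed below 0 under 4 other scalings, but the value nearest 0 was -0.323 (SE over members 0.188), within 2 SE of that bound, and the list's call was lost under all 4. Epidermal cells in the E12 material also stay open. Krt5 and Ivl, keratinocyte genes outside the list, differed by -0.0819 (SE 0.297), a value within 2 SE of both 0 and the bound of -0.377. Ivl was above background on 1 of 3 E12 arrays and on neither E18 array, so it could hardly show a fall. A change with stage in the kidney itself is untested.

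Il17b was lower at later stages. Normalization is argued against, since the slope nearest 0 under 4 other scalings was -0.422 (adjusted p between 0.00044 and 0.0281 over these scalings). The 3 arrays of highest background stay open: without them the slope was -0.395 (SE 0.0568) against -0.505 (SE 0.0562) with them, and its adjusted p of 0.0668 missed the threshold set beforehand, with 1 array left at E16 and E18. Values at E16 and E18 lie near or below background, which limits what these slopes can exclude. A change with stage, the biological difference of the design, is untested.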
